A study of Mus musculus with 6 samples.

How the data were processed

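Total RNA was extracted with TRIzol from whole mouse brain at E18.5, late in gestation, with 3 brains combined in each tube before extraction, per the labels' protocols. There were 6 libraries, 3 from wild-type (WT) embryos and 3 from embryos carrying the S156A form of PME-1, and all were made with a directional (strand-keeping) MGIEasy kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Each library is a pool of different brains, so the spread between libraries holds both biological and technical variation, and the spread between single embryos was not measured.

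The deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) and TPM values (transcript abundance as a share of the library) came from StringTie gene abundance tables, 1 per library, per the file headers and the submitters' processing notes. The notes name Trim Galore 0.6.6, HISAT2 2.2.1 and StringTie 2.1.5. The deposited coverage values are mean read depths per base, not normalized, per the file headers. Strand settings, annotation release and filters are not given in the sources used here. The submitters' processing notes give the human build hg38, but the rows carry mouse Ensembl gene identifiers and mouse chromosomes. Of 38135 genes matched by symbol, only 3.18% started within 1000 bases of their GRCm38 position, and 2 scaffolds named in the files carry names used in GRCm39. Coordinates are therefore given as the files have them, with GRCm39 as the inferred build, and no reference coordinates were mixed in.

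The deposited tables hold rows of annotated genes and, apart from these, between 26631 and 28575 rows of assembled loci per library. The TPM of the assembled rows alone add up to the full total of a library, and those of the annotated rows to between 93.1% and 95.8% of that. Only the 55359 annotated genes were used, and the 7 gene identifiers found on more than 1 row were summed. The tables hold no read counts. Depth was estimated from the ratio of coverage to FPKM, which in StringTie equals the aligned gigabases. Between 12.3% and 13.3% of rows with an FPKM above 10 sat at the commonest ratio, so these depths are estimates, and no counting intervals can be given. TPM is a share of a library, so transcripts that take a larger share in one library lower all other values there.

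Expression was tested on log2(TPM + 1) for the 18893 genes with a mean TPM of at least 1, with limma 3.58.1 in R 4.3.3 (linear model, eBayes with a mean-variance trend, two-sided, no covariate). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low TPM. Gene lists were tested with limma's camera on the same model, with a preset inter-gene correlation of 0.01. A list counted as past the threshold at an adjusted p under 0.05 over the 47 lists, all with at least 4 tested members. Camera compares a list with all other tested genes. Second values came from camera with an estimated correlation and from fry, which asks whether the genes of a list move, on balance, one way. Levels of Ppme1 and 4 related genes were also compared by an exact permutation test of 3 against 3 libraries, two-sided, whose smallest possible p is 0.1. Fisher's exact test, two-sided, compared the share of called genes within 10 Mb of Ppme1 with that among all other tested genes, Ppme1 left out.

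The gene lists, the tests and the naming rule were fixed before the data were examined. By that rule Ppme1, Ppp2ca, Ppp2cb, Lcmt1 and Ppp2r1a were named whatever their values. From the called genes whose groups did not overlap, the 12 with the largest change in each direction were named, leaving out names that are only identifiers. From each list described, up to 4 members with the smallest unadjusted p were named. Any other gene was chosen after its values were seen, and the text says so. Some genes that the rule names are not reported here. Alternatives chosen beforehand were FPKM in place of TPM, pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, scaling by a trimmed mean of M values, quantile normalization, TPM without mitochondrial, haemoglobin and ribosomal RNA genes, eBayes without trend and with robust estimation, library weights, the replicate number as a block, each library left out, and distances of 5 and 20 Mb. The trimmed mean was computed without weights on TPM, since the package function planned for it is made for counts. The design of the count test was not used, because the tables hold no counts.

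The limma and camera steps were tested on simulated data for the comparison of 3 S156A with 3 WT libraries, with 18893 genes that varied independently. Of 50 genes changed by a log2 fold of 0.5, 0 were called. The count was 11 of 50 at a log2 fold of 1, 36 of 50 at 2 and 46 of 50 at 3, with 0 calls of the wrong sign. Among 18679 unchanged genes 6 were called. Camera found a simulated list of 14 genes shifted by 0.8 with an adjusted p of 8.95e-17 and called 0 of the other 47 lists. Real genes of a list are correlated, which this simulation did not include.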

Results

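The series measured gene expression by RNA sequencing in whole mouse brain at E18.5, late in gestation. PME-1, encoded by Ppme1, is the methylesterase that removes the carboxyl methyl group from the catalytic subunit of protein phosphatase 2A (PP2A). In the S156A form the active-site serine is replaced by alanine. The data comprised 6 libraries, 3 WT and 3 S156A, each from a pool of 3 brains. Estimated depth was 3.15, 3.31 and 3.37 aligned gigabases in WT replicates 1 to 3. In S156A replicates 1 to 3 it was 3.87, 3.24 and 4.14 gigabases. Between 18191 and 19270 annotated genes reached a TPM of 1 in a library.

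Ppme1 (ENSMUSG00000030718.10, chromosome 7, 99975944 to 100021514 in the files' coordinates) was expressed in all 6 libraries. Its level was 87.1 ± 11.5 TPM in WT (SD, n = 3) and 81.4 ± 8.37 TPM in S156A (SD, n = 3). The log2 difference of -0.09 (SE 0.14) was within the spread between libraries (limma adjusted p = 0.80; exact permutation p = 0.5, smallest possible 0.1). A point mutation need not alter the level of its transcript, so this value does not check the genotype labels. Ppp2ca and Ppp2cb, the genes of the PP2A catalytic subunit, had log2 differences of -0.03 (SE 0.14) and 0.11 (SE 0.16). Lcmt1, the methyltransferase that opposes PME-1, stood at 73.7 ± 9.83 TPM in WT and 73.7 ± 7.87 TPM in S156A (SD, n = 3 each). The scaffold gene Ppp2r1a had a log2 difference of -0.24 (SE 0.13; limma adjusted p = 0.47). Of the 14 genes in the list of PP2A catalytic, scaffold and methylation genes, 0 were called over all genes or when adjusted over the list alone. Anp32a and Set, whose proteins inhibit PP2A, were the 2 genes with an unadjusted p under 0.05, with log2 differences of 0.43 and 0.31. Of the 15 regulatory subunit genes 0 were called over all genes, and 2 passed when adjusted over the list alone, Ppp2r5c with a log2 difference of 0.38 and Ppp2r2c with -0.52. Neither list stood apart from other genes (camera adjusted p = 0.55 and 0.69). Ppme1 and Lcmt1 overlap genes on the opposite strand (C2cd3 and Arhgap17), so their values are less certain if the authors' counting ignored strand.

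The comparison of S156A with WT asks which transcripts differ in the late embryonic brain when PME-1 carries the catalytic-site change. In S156A brains, genes that rose included Cx3cr1, Trem2, Gfap and Gpr17, and genes that fell included Nefl, Nefh, Slc6a7, Slc6a5 and Thy1. Of 18893 genes tested, 30 were called by limma, 16 higher and 14 lower in S156A, and for each of the 30 the groups did not overlap. The adjusted p of the called genes lay between 0.028 and 0.048, close to the threshold. At an unadjusted p under 0.05 there were 2628 genes, against 945 by chance. Among all tested genes 20.8% had groups that did not overlap, against 10% by chance.

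The microglial fractalkine receptor Cx3cr1 rose from 4.89 ± 0.71 to 23.7 ± 2.59 TPM (SD, n = 3 each), a log2 change of 2.07 (SE 0.18). Trem2, a lipid-sensing receptor of microglia, rose from 6.35 ± 1.39 to 27.4 ± 6.59 TPM, and Fcrls from 11.7 ± 0.87 to 41.7 ± 6.60 TPM. Other myeloid genes among the calls were Cd180 (log2 change 2.21), Mpeg1 (1.87), Ly86 (1.71), Fcer1g (1.55) and Laptm5 (1.44). Gfap, the intermediate filament of astrocytes, rose from 21.2 ± 2.25 to 109 ± 33.9 TPM, a log2 change of 2.26 (SE 0.24). Gpr17, a receptor of differentiating oligodendrocyte precursors, rose from 12.6 ± 1.74 to 31.8 ± 2.71 TPM. The cholesterol exporter Abca1 rose from 18 ± 1.13 to 45.6 ± 6.57 TPM. Dock1, an exchange factor for Rac used in phagocytosis, rose from 1.29 ± 0.59 to 10.2 ± 1.57 TPM. Among the other 4 genes that rose, Jun and Ctsb changed by 1.15 and 0.85 on the log2 scale, and Ctsb was named after its value was seen.

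The neurofilament light chain Nefl fell from 264 ± 17.8 to 102 ± 5.32 TPM, a log2 change of -1.37 (SE 0.10), and the heavy chain Nefh from 17.1 ± 0.69 to 4.93 ± 0.81 TPM. The medium chain Nefm also fell (log2 change -0.97, named after its value was seen, as was AW551984 with -1.05). Slc6a7, the brain proline transporter, fell from 49.3 ± 9.80 to 11.6 ± 0.55 TPM. Slc6a5, the glycine transporter of inhibitory hindbrain and spinal neurons, fell from 10.2 ± 0.88 to 2.48 ± 0.34 TPM. Thy1, a surface glycoprotein of maturing neurons, fell from 77.6 ± 8.55 to 26.9 ± 4.53 TPM. The neuropeptide precursor Vgf fell from 71.7 ± 8.40 to 23.3 ± 4.16 TPM. Among the called genes the largest decrease on the log2(TPM + 1) scale was in Thsd7b, from 7.36 ± 0.85 to 0.49 ± 0.04 TPM (log2 change -2.48). Over the alternative settings its change ran from -3.66 to -1.17, and that of Cpne7 from -2.27 to -1.51, so this rank depends on the setting. Cpne7 (-2.03), the potassium channel gene Kcnc4 (-1.47), the G protein subunit gene Gng4 (-1.47), the calcium sensor gene Vsnl1 (-1.27) and Hoxb5 (-1.18) completed the calls. Cx3cr1 and Cpne7 overlap other tested genes on the same strand, so their values are less certain. Nefl, Dock1, Cd180, Gpr17, Thsd7b and Cx3cr1 overlap genes on the opposite strand, and whether the authors' counting used strand is not given in the sources used here.

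The number of calls depended on the libraries and on scaling. All 30 genes kept an unadjusted p under 0.05 with any 1 library left out, but they were chosen from these same libraries. Their groups did not overlap, so their direction could not turn in these fits. The count was 2, 0 and 70 without WT replicate 1, 2 and 3, and 1, 0 and 0 without S156A replicate 1, 2 and 3, with 1535 to 2260 genes at an unadjusted p under 0.05 in the 3 cases with 0 calls. Scaling by a trimmed mean of M values gave 17 higher and 58 lower, quantile normalization 16 and 36, and FPKM 13 and 24, in place of 16 and 14.

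**Figure D1:**
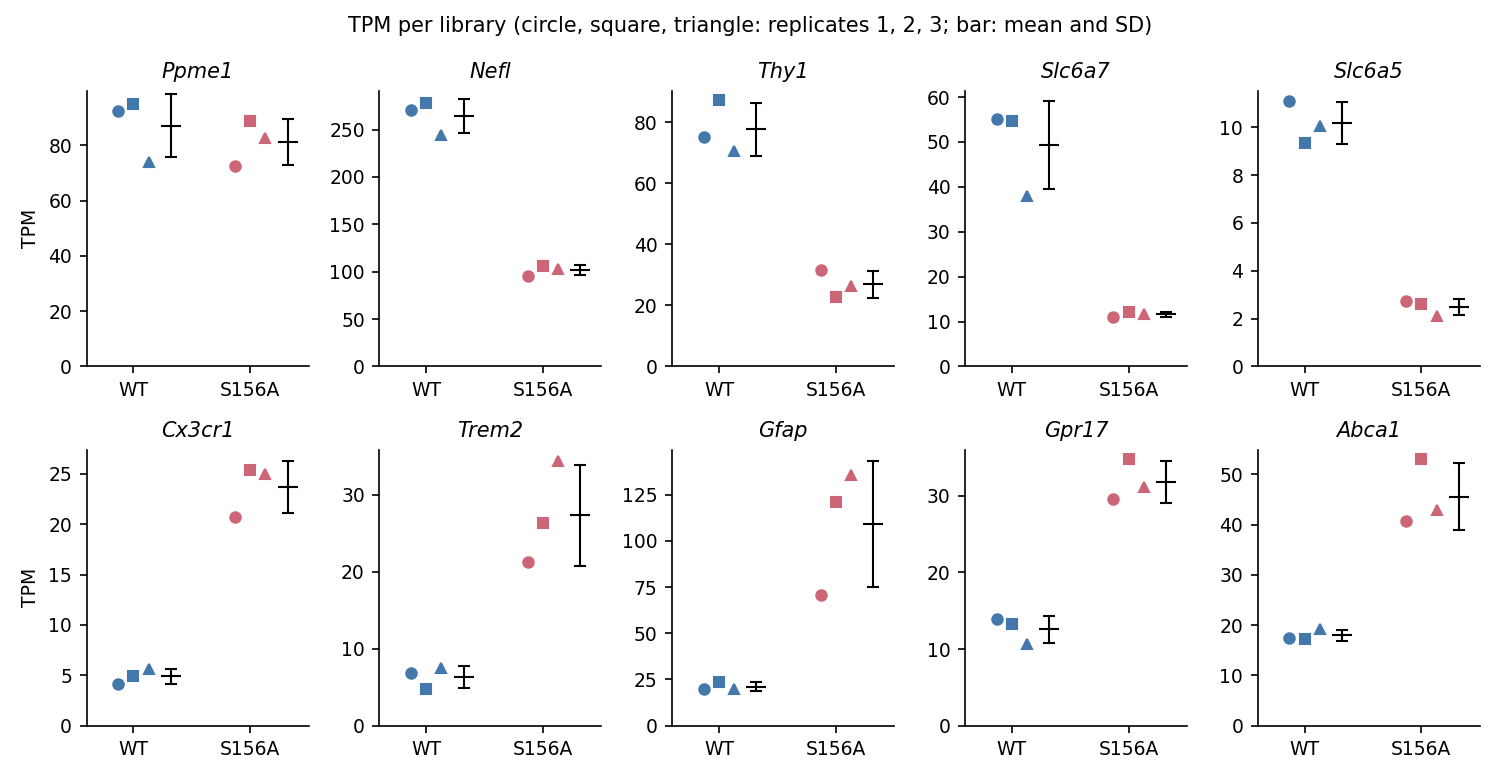
TPM (linear axis from 0) of Ppme1 and 9 called genes in WT and S156A, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3) and a bar for the mean and SD of 3 libraries. The groups overlap for Ppme1 and are separate for the 9 called genes, as for Nefl at 264 against 102 TPM.

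Of the 47 gene lists, 19 passed camera with the preset correlation, 10 higher and 9 lower in S156A relative to other genes. With an estimated correlation 0 of the lists passed, the smallest adjusted p being 0.21. Fry called 10 lists. The median log2 difference of all tested genes was 0.09.

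The microglia list rose: all 14 members had higher values in S156A, with a median log2 difference of 1.46 (camera adjusted p = 1.56e-15; adjusted p = 0.21 with an estimated correlation). Of these 14 genes 5 were called, Cx3cr1, Fcrls, Laptm5 and Trem2 among them, and 12 passed when adjusted over the list alone. Astrocyte markers rose (median 0.49 over 14 genes, camera adjusted p = 2.81e-04; adjusted p = 0.29 with an estimated correlation), with Gfap called and 6 genes past the threshold when adjusted over the list alone. Apoe, the main apolipoprotein gene of astrocytes, was at 566 ± 60.8 TPM in WT and 1428 ± 376 TPM in S156A. Oligodendrocyte lineage markers rose (median 0.59 over 13 genes, camera adjusted p = 0.0019; adjusted p = 0.21 with an estimated correlation), with Gpr17 called and 7 genes past the threshold when adjusted over the list alone. Among them the myelin gene Mbp was at 31.0 TPM in WT and 99.2 TPM in S156A, and Bcas1 at 1.70 and 14.5 TPM. Erythroid markers also passed camera (median 0.52 over 7 genes, adjusted p = 0.046; adjusted p = 0.63 with an estimated correlation), with 0 genes called either way and Hbb-bs at 4789 ± 1834 TPM in WT and 6529 ± 850 TPM in S156A. The erythroid list did not pass without WT replicate 1 or 2 or S156A replicate 1 or 3 (camera adjusted p of 0.073 to 0.38). Endothelial (median 0.11) and mural cell (median 0.24) markers did not pass (camera adjusted p = 0.49 and 0.23). Blood leukocyte and border macrophage markers, lists added after the data were seen, had mean log2 differences of 0.77 (SE 0.38) and 0.70 (SE 0.54), with 0 genes called and 3 and 2 at an unadjusted p under 0.05.

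Lists of proliferating and ventricular cells were higher in S156A. Intermediate progenitor markers rose (median 0.66, all 7 genes higher, camera adjusted p = 2.81e-04; adjusted p = 0.21 with an estimated correlation), and 6 passed when adjusted over the list alone, with Eomes at 16.6 TPM in WT and 26.0 TPM in S156A. Cell cycle genes rose (median 0.42, 26 of 28 higher, camera adjusted p = 6.06e-07; adjusted p = 0.47 with an estimated correlation), with 0 passing when adjusted over the list alone. Radial glia markers rose (median 0.33 over 13 genes, camera adjusted p = 0.012; adjusted p = 0.34 with an estimated correlation), Nes being at 37.0 TPM in WT and 52.6 TPM in S156A. This list did not pass without S156A replicate 2 or 3 (camera adjusted p = 0.053 in each case). Choroid plexus markers rose (median 0.75, all 12 genes higher, camera adjusted p = 1.05e-06; adjusted p = 0.21 with an estimated correlation), and 8 passed when adjusted over the list alone. Ttr, the thyroxine carrier secreted by the choroid plexus, was at 1223 ± 226 TPM in WT and 2611 ± 631 TPM in S156A. Ependymal and cilia genes rose (median 0.80 over 10 genes, camera adjusted p = 0.0014; adjusted p = 0.29 with an estimated correlation), with the ciliogenesis factor Foxj1 at 20.8 and 38.9 TPM, and did not pass without S156A replicate 1 (camera adjusted p = 0.052). None of the genes in these 5 lists was called over all genes.

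Lists of subcortical neurons were lower in S156A. Dopaminergic markers fell (median -0.59, all 12 genes lower, camera adjusted p = 1.05e-06; adjusted p = 0.21 with an estimated correlation), and 4 passed when adjusted over the list alone. Th, the rate-limiting enzyme of dopamine synthesis, was at 11.1 ± 3.43 TPM in WT and 1.91 ± 0.53 TPM in S156A. Serotonergic markers fell (median -0.56 over 7 genes, camera adjusted p = 2.57e-04; adjusted p = 0.27 with an estimated correlation). The serotonin transporter Slc6a4 was at 11.4 ± 4.12 TPM in WT and 1.14 ± 0.72 TPM in S156A, and 3 of these genes passed when adjusted over the list alone. Thalamic markers fell (median -0.76 over 10 genes, camera adjusted p = 6.42e-07; adjusted p = 0.29 with an estimated correlation), with 6 past the threshold when adjusted over the list alone and Slc17a6, a vesicular glutamate transporter, at 81.3 and 39.4 TPM. Hypothalamic neuropeptide genes fell (median -0.52 over 15 genes, camera adjusted p = 2.81e-04; adjusted p = 0.29 with an estimated correlation), with 3 past the threshold when adjusted over the list alone and Oxt at 2.55 and 0.30 TPM. Hindbrain and Hox genes fell (median -0.58 over 17 genes, camera adjusted p = 6.57e-09; adjusted p = 0.23 with an estimated correlation), with Hoxb5 called and 6 past the threshold when adjusted over the list alone. Hoxc4 was at 12.8 TPM in WT and 5.09 TPM in S156A. Synapse genes fell (median -0.45 over 24 genes, camera adjusted p = 4.50e-10; adjusted p = 0.34 with an estimated correlation), with 0 called, 9 past the threshold when adjusted over the list alone and the synaptic vesicle gene Syp at 338 and 190 TPM. Markers of glutamatergic cortical neurons had a median of 0.25 and did not pass (camera adjusted p = 0.086), with Neurod2 at 100 TPM in WT and 173 TPM in S156A. GABAergic, striatal and cerebellar markers, with medians of 0.29, -0.08 and -0.06, did not pass (camera adjusted p = 0.23, 0.094 and 0.24).

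Genes of cholesterol synthesis fell as a list, with all 19 members lower in S156A (median log2 difference -0.87, camera adjusted p = 1.06e-18; adjusted p = 0.23 with an estimated correlation). None was called over all genes, and 16 passed when adjusted over the list alone. Mvd, of the mevalonate pathway, was at 66.5 ± 13.7 TPM in WT and 28.8 ± 2.92 TPM in S156A (SD, n = 3 each). Mvk, of the same pathway, was at 67.8 ± 12.9 TPM in WT and 32.4 ± 4.0 TPM in S156A. Mitochondrially encoded protein genes (median -0.21, all 13 lower, camera adjusted p = 5.49e-04; adjusted p = 0.43 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.08 over 58 genes, camera adjusted p = 9.42e-04; adjusted p = 0.70 with an estimated correlation) were lower by small amounts. The nuclear list did not pass without WT replicate 3 or S156A replicate 2, where its mean was 0.0146 and 0.0135 (camera adjusted p = 0.36 and 0.64). Endoplasmic reticulum chaperone genes were slightly higher (median 0.17 over 16 genes, camera adjusted p = 0.037; adjusted p = 0.42 with an estimated correlation), but not without WT replicate 1 or 3 or S156A replicate 1 or 3 (camera adjusted p of 0.0503 to 0.139). None of the genes of these 3 lists passed when adjusted over the list alone.

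**Figure D2:**
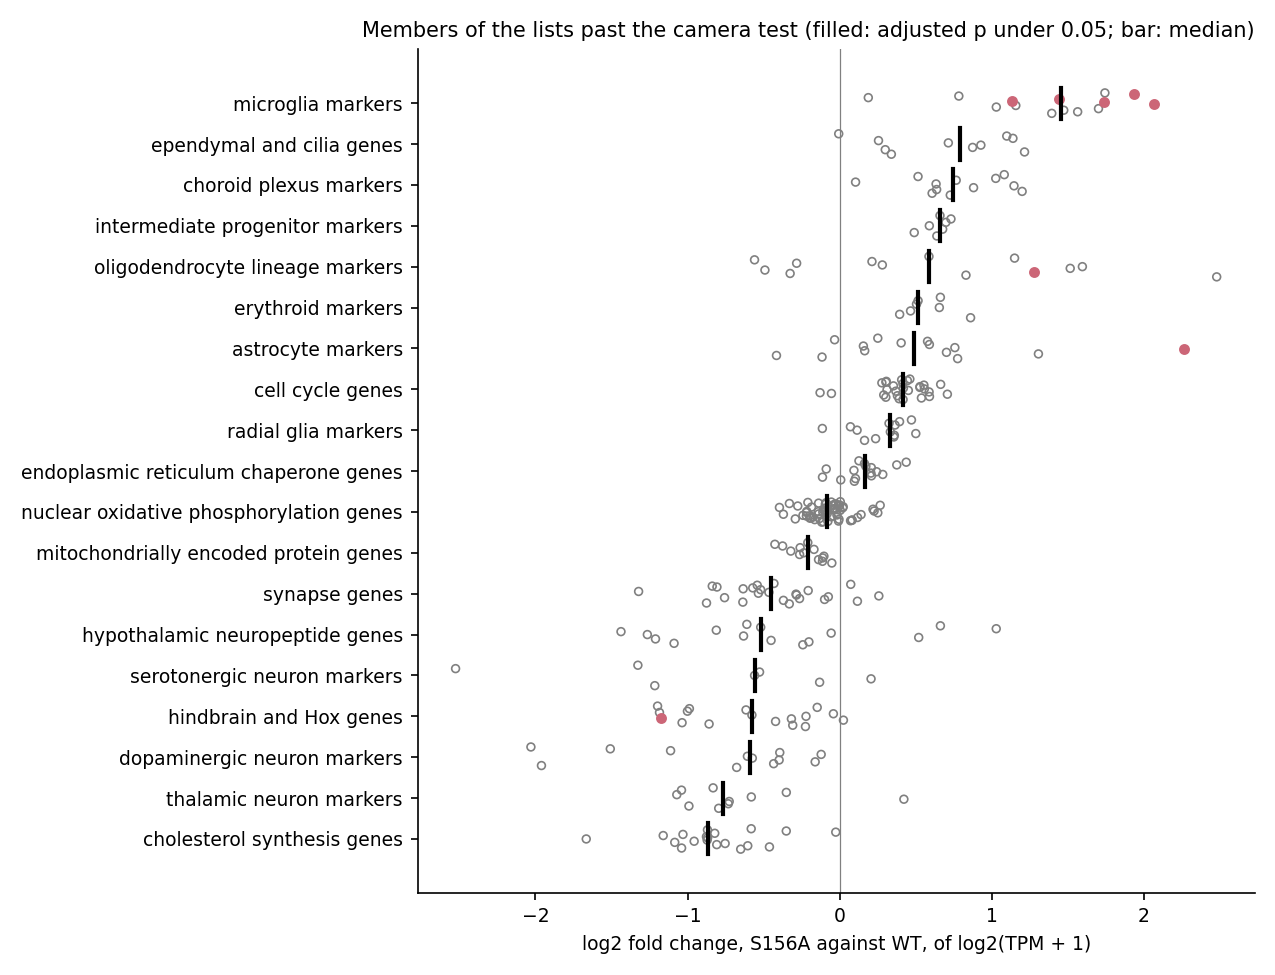
Log2 fold change of log2(TPM + 1), S156A against WT (x axis), for each tested member of the 19 lists past camera with the preset correlation, ordered by list median (black bar); filled points are genes with a limma adjusted p under 0.05. The medians run from -0.87 for cholesterol synthesis genes to 1.46 for microglia markers.

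The remaining lists did not pass, with camera adjusted p between 0.081 for interferon-response genes and 0.99 for replication-dependent histone genes. The interferon-response list passed without WT replicate 2 or 3 or S156A replicate 2 (camera adjusted p of 0.022 to 0.039). The immediate early list had a median of 0.22 (camera adjusted p = 0.15; 0.021 without WT replicate 3), with Jun called and Btg2 at 13.5 TPM in WT and 26.9 TPM in S156A. The p53 target, integrated stress response, heat shock, and hypoxia and glycolysis lists had medians of 0.21, 0.30, -0.03 and -0.0048, and the Wnt target and axon guidance lists 0.11 and -0.05. For the ERK pathway feedback and cerebellar lists the median and the test were negative and the mean was positive (0.0032 and 0.0095).

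The largest difference between libraries did not follow genotype. The first principal component held 47.0% of the variance and placed WT replicate 3 and S156A replicate 1 apart from the other libraries, and the second, with 22.2%, separated the genotypes. Genes of skeletal muscle led the first component. Acta1, the actin of skeletal muscle, was at 8.22, 333 and 2472 TPM in WT replicates 1 to 3 and at 2611, 17.7 and 18.7 TPM in S156A replicates 1 to 3. Without WT replicate 3 and S156A replicate 1, the 2 libraries with the most Acta1, a comparison chosen after the data were seen, 6 genes and 22 lists passed, and 18 of the 19 lists were among them. Pituitary markers (median 1.38 over 5 genes, 3 higher and 2 lower in S156A, camera adjusted p = 0.19) also differed between libraries. Gh, the growth hormone gene, was listed at 0, 1.69 and 97.1 TPM in WT and at 310, 166 and 130 TPM in S156A. The sex mix of the pools differed as well. Xist was at 135, 0.05 and 68.8 TPM in WT replicates 1 to 3 and at 239, 236 and 91.6 TPM in S156A replicates 1 to 3, and the Y-linked gene Ddx3y was at 0.27 TPM in S156A replicate 1 and between 9.86 and 19.6 TPM in the others. With the mean of 4 Y-linked genes as a covariate, also chosen after the data were seen, 0 genes were called by limma (1742 at an unadjusted p under 0.05) and 21 lists passed camera.

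**Figure D3:**
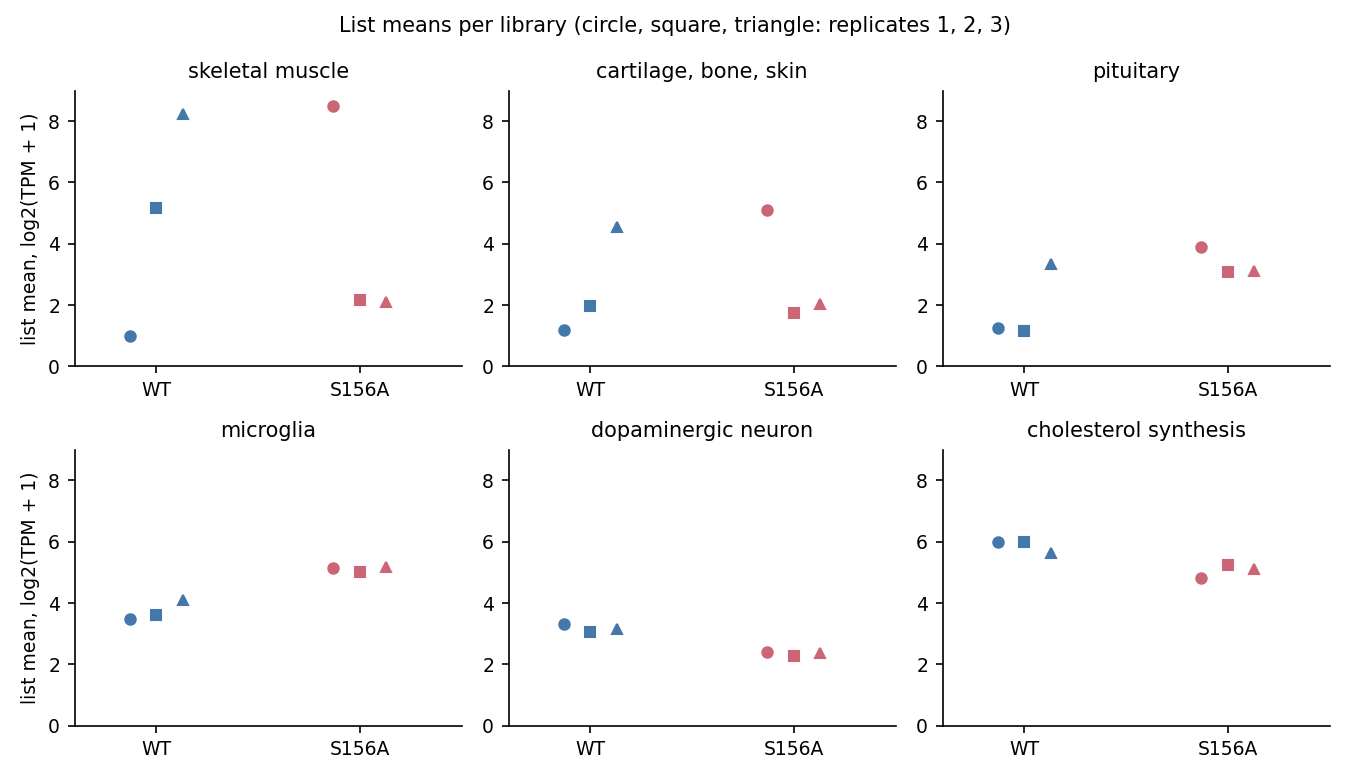
Mean log2(TPM + 1) of the members of 6 lists in each library (y axis, 0 to 9), with circle, square and triangle for replicates 1, 2 and 3. Skeletal muscle markers stand at 8.22 in WT replicate 3 and 8.49 in S156A replicate 1 against 1.00 to 5.16 elsewhere, while the microglia, dopaminergic and cholesterol synthesis lists separate the genotypes.

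A knock-in allele can carry flanking sequence from another strain, so genes near Ppme1 were examined. Of 172 tested genes within 10 Mb of Ppme1, 0 were called by limma, against 30 of the 18720 other genes (Fisher's exact test p = 1; 95% confidence interval of the odds ratio 0 to 14.4). At an unadjusted p under 0.05 there were 32 of 172 against 2596 of 18720 genes, an odds ratio of 1.42 (Fisher's exact test p = 0.077).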

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

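The alternatives without the 2 libraries with the most muscle transcripts (WT replicate 3 and S156A replicate 1), with a head tissue or Y-linked covariate and with TPM of annotated genes rescaled to a common total were chosen after the data were seen; the others were fixed before. All 30 called genes kept their direction and an unadjusted p under 0.05 in every setting that tested them (28 were tested at a mean TPM of at least 5). The count of calls moved: 0 with no filter (36715 genes tested, 3364 at an unadjusted p under 0.05), 75 with a trimmed mean of M values, 52 with quantile normalization, 16 without trend, 309 with library weights, 6 without those 2 libraries, 372 with the head tissue covariate, 0 with the Y-linked covariate, and 0 to 70 with 1 library left out. Leaving out libraries also lowers the number of samples, and the cause of these moves was not tested. The replicate number as a block gave 0 genes (1880 at an unadjusted p under 0.05) and 18 lists. Deviations of same-numbered libraries correlated at -0.55, 0.19 and -0.41. Those of WT replicate 3 and S156A replicate 1, the 2 libraries with the most muscle transcripts, correlated at 0.65. Both libraries enter the same-numbered values, so these cannot show whether the numbers pair the libraries.

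The count of lists stayed between 16 and 23 in all settings of the preset camera test, 17 to 23 with 1 library left out, and was 0 with an estimated correlation and 10 with fry. The microglia, cholesterol synthesis, synapse, cell cycle, dopaminergic, thalamic and hindbrain lists passed in all 23 settings, ependymal in 22, radial glia in 21, nuclear oxidative phosphorylation in 20, the erythroid list in 12 of 22 and the endoplasmic reticulum chaperone list in 11 of 23. With 1 library left out, calls were lost for the ependymal list (without S156A replicate 1), radial glia (S156A replicate 2 or 3), nuclear oxidative phosphorylation (WT replicate 3 or S156A replicate 2), erythroid (WT replicate 1 or 2, S156A replicate 1 or 3) and chaperone (WT replicate 1 or 3, S156A replicate 1 or 3). The nuclear oxidative phosphorylation mean ran from -0.171 to 0.0146. Ppme1 was not called in any setting (log2 difference -0.21 to -0.01, both with 1 library left out).

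The differences of Lcmt1 and Ppp2ca, near 0 and never called, changed sign, and the cause was not tested. Lcmt1 was at -0.0170 with FPKM, -0.0933 with the trimmed mean, -0.0281 with quantile normalization, -0.0079 without mitochondrial, haemoglobin and rRNA genes, -0.0430 without those 2 libraries, -0.00777 with the Y-linked covariate, -0.00645 with rescaled TPM, and -0.0897 to 0.0995 with 1 library left out. Ppp2ca was at 0.0261 without those 2 libraries, 0.0731 with the Y-linked covariate, and -0.103 to 0.0956 with 1 library left out. For the PP2A lists the direction of the camera test, relative to other genes, turned in some settings. The mean of the PP2A catalytic, scaffold and methylation list was -0.00842 with the trimmed mean and 0.0437 to 0.158 with 1 library left out, and that of the regulatory subunit list 3.06e-04 and 0.0389 to 0.150. The odds ratio for genes near Ppme1, taken at an unadjusted p where under 10 genes were called, was 1.18 with no filter, 1.47 with the replicate block, 1.29 without those 2 libraries, 1.01 with the Y-linked covariate and 0 to 1.51 with 1 library left out (Fisher's exact p of at least 0.070 throughout). Without read counts, the depth limits of single values are unknown.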

Other observations

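The tests of head tissue, of endothelial markers, of cortical markers and of the regional lists in separate parts were chosen after those values were seen, as was taking the gap between a marker list and its pattern per library; the other tests below were written before theirs. Within the oligodendrocyte lineage list, members differed in direction, with 9 higher and 4 lower in S156A. Gpr17, of differentiating precursors, was higher (log2 change 1.28), and no contrast of stages was tested. Mbp and Mag, genes of myelinating cells, had log2 differences of 1.60 and 1.52, while Pdgfra and Cspg4, genes of precursors, had -0.56 and -0.32, and none of these 4 was called by limma over all genes (Mag, Pdgfra and Cspg4 were picked after their values were seen). Among 14 telencephalic transcription factors, 12 were higher in S156A, with a mean difference of 0.31 (SE 0.15) and 0 called by limma (4 at an unadjusted p under 0.05). Rn18s, a ribosomal RNA gene, was at 18533 TPM in WT replicate 2 and at 4050 to 6853 TPM in the other libraries.

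Dopaminergic, serotonergic, thalamic, hypothalamic and hindbrain lists were lower together in S156A, with a mean difference of -0.64 (SE 0.07) over 61 genes. Without WT replicate 3 and S156A replicate 1 the difference was -0.71 (SE 0.08), so it did not rest on the head tissue in these libraries. They were 1 of each genotype, with similar skeletal muscle list means of 8.22 and 8.49. Leaving them out could therefore hardly shrink the difference, and WT replicate 2, at 5.16, was kept. Head tissue in general is thus not decided by this comparison. An equal loss of neurons across regions is argued against by the cortical list, which differed by 0.25 (SE 0.18). Pan-neuronal genes differed by -0.24 (SE 0.17) and fell less than the 5 lists by 0.41 (SE 0.17). By themselves they are too imprecise to exclude a smaller neuron share as a contributor. A smaller share of midbrain and hindbrain tissue in the S156A pools is argued against for the thalamic and hypothalamic lists, which are of the forebrain and whose difference less that of 22 midbrain and hindbrain transcription factors was -0.38 (SE 0.12). The dopaminergic, serotonergic and hindbrain lists differed by -0.73 (SE 0.11). Those transcription factors, at -0.14 (SE 0.09), fell less than these lists by 0.59 (SE 0.19), which argues against a smaller tissue share as the only source. The bound for excluding it was a fall under 1/2 that of these lists. The transcription factors lay past that bound by 0.22 (SE 0.14), under 2 standard errors. As a contributor, a smaller tissue share therefore cannot be told apart from an effect of the genotype. Other dissection differences were not tested.

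The microglia list was higher by 1.38 (SE 0.19). A smaller share of neurons would raise other cell types alike. The endothelial list, at 0.14 (SE 0.22), argues against it as the only source. Other lists differed unevenly, with means of 0.20 for mural, 0.53 for astrocyte, 0.64 for oligodendrocyte and 0.78 for choroid plexus markers. A smaller share of neurons therefore stays open as a contributor. Blood leukocytes stay open as a contributor: 9 of their markers differed by 0.77 (SE 0.38), from 0.01 for S100a8 to 2.30 for Cd52, below the microglia list by 0.61 (SE 0.25) and too imprecise to exclude them. Border macrophages, with 9 markers differing by 0.70 (SE 0.54), cannot be told apart from microglia at this precision. An effect of the genotype on microglia was not tested apart from these sources.

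Cholesterol synthesis genes were lower, with a list mean difference of -0.81 (SE 0.17). The difference was -0.82 (SE 0.08) without WT replicate 3 and S156A replicate 1, the 2 libraries with the most muscle transcripts, so it did not rest on them. As they were 1 of each genotype with similar muscle levels, this does not decide on head tissue in general. An equal loss of neurons across regions is argued against by the cortical list at 0.25 (SE 0.18). Pan-neuronal genes, at -0.24 (SE 0.17), fell less than the cholesterol list by 0.58 (SE 0.05). This argues against a smaller share of neurons as the only source, and as a contributor it stays undecided. With Abca1 higher, higher sterol sensing through liver X receptors may be a hypothesis. As a mean, 10 of their other target genes, taken only from outside the fixed gene lists, differed by 0.11 (SE 0.09), which does not decide it. Of these 10 genes 8 were higher, Abcg1 by 0.68 on the log2 scale, while Scd1 (-1.26) and Scd2 (-0.43) were lower.

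The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 30 called genes, and it was the only 1 of the 10 splits to give as many; the highest other split gave 2. For gene lists, the other splits gave between 7 and 19. In all, 2 of the 10 splits gave as many as the real 19, the highest other also giving 19. That split set the 2 libraries with the most muscle transcripts and S156A replicate 3 against the rest, so the number of lists past camera with the preset correlation also follows the structure of the libraries.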
